A study of Mus musculus with 8 samples.

How the data were processed

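RNA was sequenced in 8 libraries of mouse granulosa cells, the follicle cells that surround the oocyte. Per the labels, the cells came from C57BL/6J ovaries 3 days after PMSG, a gonadotropin that stimulates follicle growth, and were immortalised with SV40. Libraries were made with a stranded mRNA kit and sequenced on a HiSeq 2500 as 150-bp paired ends from cells collected 48 h after transfection, per the labels' protocols. The series title speaks of a goat single-nucleus atlas, which is not analysed here. Groups and replicate numbers follow the sample titles, with 4 libraries called Con and 4 called OP. Whether the replicates were separate cultures is not given in the sources used here, so p-values measure the spread between these libraries, which may be technical.

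The labels do not settle what OP received. The protocol describes both a lentivirus carrying the SERPINE2 coding sequence and siRNAs against SERPINE2, while the transfection label of the OP libraries names the siRNAs. Groups were kept as titled and were not redefined from the values.

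The authors deposited a table of whole-number read counts per gene and a table of FPKM (fragments scaled by gene length and library total) for the same 17182 genes, per the file headers. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm9 without a role; the counting tool, its strand setting, the annotation and any filter are not given in the sources used here. The deposited FPKM equalled the count divided by a fixed length per gene and by the library's column sum, for all 121854 values above 0 at a relative tolerance of 1e-06. Because the build is unclear, no coordinates are printed. Reference tables of assembly GRCm38 served only for gene names, chromosome assignment and GC content, and 17077 gene identifiers matched.

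Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit, glmQLFTest), with TMM scaling, genes kept by filterByExpr, Benjamini-Hochberg adjustment and a threshold of 0.05. This left 12690 tested genes holding at least 99.9% of the reads of each library. Log2 fold changes are OP over Con, and each standard error was derived as the absolute log2 fold change divided by the square root of the F statistic. CPM (counts scaled to the library total) were TMM-scaled, and log2 CPM used a prior count of 2. Serpine2 also had a two-sided exact permutation test over the 70 assignments of libraries to groups. On simulated data with 4 against 4 libraries and 12619 tested genes, the test recovered 82.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, with 13 false calls among 196.

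Before the data were examined, 29 gene lists were fixed for granulosa functions, other ovarian cell types, proteolysis, signalling, stress and proliferation. The lists held 742 genes, of which 708 were in the table, 27 of them under another symbol. The 24 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and also with an estimated correlation and with fry. The rule for named genes, fixed at the same time, took Serpine2, the 10 largest rises and 10 largest falls among genes past the threshold with average log2 CPM of at least 1 and no overlap between groups, up to 4 called genes of lowest p per list, and a fixed set of anchor genes. Predicted genes without an established symbol were passed over in the rises and falls, and 18 such genes qualified. Some genes the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

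The alternatives planned were RLE, upper-quartile or library-size scaling, no or a stricter low-count filter (CPM of at least 1 in 4 libraries), DESeq2 1.42.0, limma-voom with and without quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, a test against a fold of 1.5, an adjusted p of 0.01 and leaving out each library. Analyses without Con replicate 4 beyond the planned counts, and those of the deposited KEGG and GO annotation, were added after seeing the data. Library totals were 17731048 to 19441504 reads, and counts from replicate pairs differed by more than sampling noise in every pair, so none was treated as a duplicate.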

Results

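The series compared gene expression in immortalised mouse granulosa cells between 4 control libraries (Con) and 4 libraries labelled OP, from a study of SERPINE2. Serpine2 encodes protease nexin-1, a secreted serpin that inhibits thrombin, urokinase and tissue plasminogen activator. Total counts ranged from 17731048 to 19441504 reads per library, and 14977 to 15426 genes had at least 1 read.

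Serpine2 (Entrez gene 20720) was higher in every OP library than in any Con library. Its counts were 1947, 1992, 2371 and 2432 in Con replicates 1 to 4 and 19090, 19557, 18993 and 18165 in OP replicates 1 to 4. The level was 120.8 ± 15.1 CPM in Con and 1011 ± 20.7 CPM in OP (SD, n = 4 each), an 8.37-fold difference. The log2 fold change was 3.07 with a standard error of 0.08 (edgeR quasi-likelihood test, adjusted p = 7.27e-09). The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries can give. This direction goes against the transfection label, which names siRNAs against SERPINE2 for these libraries. All directions below are therefore those of the libraries labelled OP relative to Con, whatever the cells received.

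**Figure D1:**
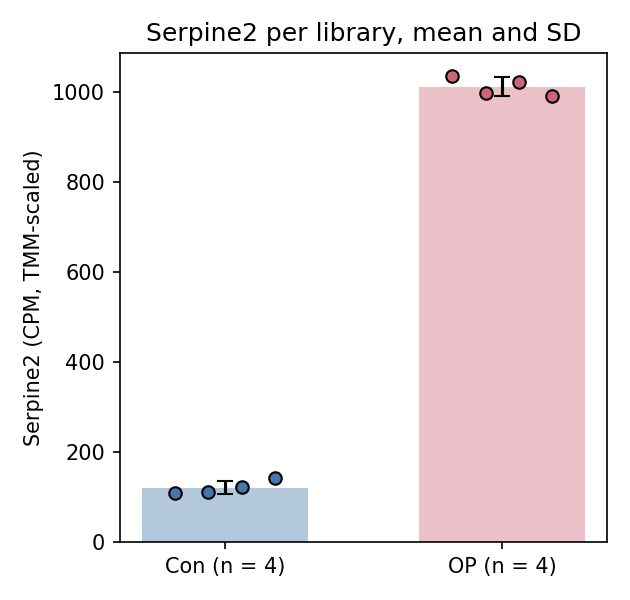
Serpine2 level in CPM (vertical axis) in the Con and OP libraries; points are libraries, bars are group means and error bars are SD (n = 4 each). The Con mean was 120.8 CPM and the OP mean 1011 CPM.

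Con and OP separated along the first principal component of log2 CPM, which held 55.7% of the variance. Con replicate 4 stood apart from the other Con libraries along the second, which held 22.1%, at -33.0 against 13.0 to 13.3. Its mean correlation with its own group was 0.985. Correlations were 0.9949 to 0.9951 among Con replicates 1 to 3 and 0.9954 to 0.9960 among the OP libraries. Relative to the other Con libraries it had more Id1, Id2 and Id3, which encode inhibitors of basic helix-loop-helix factors and are induced by BMP signalling. Id1 was at 83.8 CPM against 33.3 ± 2.93, Id2 at 54.7 against 20.7 ± 2.35 and Id3 at 109.4 against 40.7 ± 3.57 (SD, n = 3). It had less Adamts5, a proteoglycan-cleaving protease, at 57.3 CPM against 180.6 ± 4.74, and less Igf1 at 3.15 against 11.9 ± 1.17. These genes were chosen after their values were seen.

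**Figure D2:**
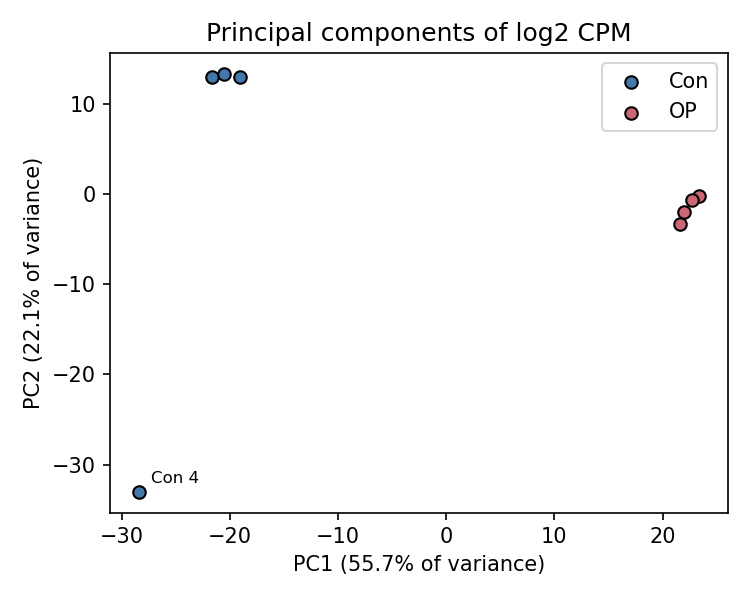
First and second principal components of log2 CPM over the tested genes, with the share of variance on each axis; each point is a library. The OP libraries lie together, and Con 4 lies at -33.0 on the second component, away from the other Con libraries at 13.0 to 13.3.

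Large changes were mostly rises in OP of genes with little expression in Con: of the 135 rises of at least 4-fold, 106 were of genes with a Con mean below 1 CPM. Of 12690 tested genes, 927 rose and 694 fell (edgeR quasi-likelihood test, adjusted p below 0.05). At least 2-fold changes numbered 292 rises and 15 falls, and at least 4-fold changes 135 rises and 2 falls. The median called rise was 0.56 and the median called fall -0.25 on the log2 scale. The 4 OP libraries lay above all Con libraries for 11.9% of tested genes and below for 11.2%, against 1.43% expected by chance each way. Without Con replicate 4, 2382 genes rose and 2292 fell, and 924 of the 927 rises and all 694 falls were called again. Leaving out OP replicate 1, 2, 3 or 4 gave 366, 321, 341 or 330 falls.

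The 10 largest rises under the naming rule were Lrrc17, Ifi206, Nos1, Ifi213, Dock10, Acap1, Disp2, Unc5a, Pax9 and En2. Lrrc17, a secreted leucine-rich repeat protein, went from 0.106 ± 0.110 to 4.01 ± 0.455 CPM (SD, n = 4), a log2 fold change of 5.10 with a standard error of 0.37. It had 1, 2, 5 and 0 reads in Con replicates 1 to 4, and its log2 fold change was 5.98 without Con replicate 3 and 1.44 on the log2(FPKM + 1) scale, which compresses low genes. Nos1, the neuronal nitric oxide synthase, rose by a log2 fold change of 4.55, from 0.153 to 3.71 CPM. Unc5a, a netrin receptor, rose from 0.317 ± 0.0650 to 4.71 ± 0.216 CPM. The developmental transcription factors Pax9 and En2 reached 6.95 ± 1.03 and 7.51 ± 0.686 CPM, from 0.539 and 0.632. Dock10, a guanine nucleotide exchange factor, rose from 0.337 to 6.80 CPM, and Acap1 and Disp2 had log2 fold changes of 4.13 and 4.12. Ifi206 and Ifi213 had log2 fold changes of 4.67 and 4.53. Ifi206 had 8, 17, 1 and 1 reads in Con replicates 1 to 4, and without Con replicate 2 its value was 5.66. Both belong to a cluster of similar interferon-activated genes, so the assignment of reads between copies is uncertain.

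The 10 largest falls under the same rule were shallower. Fgb, which encodes the fibrinogen beta chain, went from 3.49 ± 1.89 to 1.19 ± 0.289 CPM, a log2 fold change of -1.54 (adjusted p = 0.0235). Apob and Gc, which encode an apolipoprotein and the vitamin D-binding protein, had log2 fold changes of -1.07 and -0.96. Alpl, an alkaline phosphatase, Sprr1a, a small proline-rich protein, and Trabd2b, a membrane protease that inactivates Wnt proteins, had log2 fold changes of -1.09, -1.22 and -0.90. Without Con replicate 4 these last values were -0.70, -0.65 and -0.65. Chst8, a sulfotransferase, fell from 16.7 ± 2.29 to 8.56 ± 0.578 CPM. Tnnc1, Cd24a and Ncald had log2 fold changes of -0.97, -0.96 and -0.88. The calls of Fgb and Alpl were lost when any OP library was left out (adjusted p up to 0.0761 and 0.0733), and that of Sprr1a also without Con replicate 1 (up to 0.122). Gc was lost without OP replicate 1, 2 or 3 (up to 0.0644), Ncald without OP replicate 1 or 3 (0.0558), Cd24a without OP replicate 3 or 4 (0.0603) and Tnnc1 without any library but Con replicates 1 and 4 (0.0598). Fgb, Apob and Gc are liver-expressed genes, and liver transcripts were present in every library: a set of 20, chosen after values were seen, summed to 89.5 ± 31.8 CPM in Con and 62.5 ± 7.12 CPM in OP. Within that set, which includes Fgb, Apob and Gc themselves, 6 fell, 0 rose and the others did not pass. Major urinary protein genes, also expressed in liver, lay outside the set and had 27 to 54 reads in Con and 183 to 264 in OP.

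Y-linked transcripts were also higher in OP. The summed level of Ddx3y, Eif2s3y, Kdm5d and Uty, chosen after their values were seen, was 1.91 ± 0.244 CPM in Con and 11.7 ± 1.31 CPM in OP (SD, n = 4). Their X-linked homologs Ddx3x, Eif2s3x, Kdm5c and Kdm6a had log2 fold changes of -0.04, -0.15, -0.03 and -0.10, none past the threshold. The Y-linked gain equalled 1.09% of the summed Con level of these homologs.

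Genes of granulosa identity moved both ways. Of 14 tested granulosa markers, 4 rose and 4 fell, and adjusted over the list alone the counts were the same. Among the risers were Serpine2 itself and Nr5a1, a nuclear receptor that drives steroidogenic genes, from 0.814 ± 0.260 to 3.98 ± 0.547 CPM. Inhbb, the inhibin beta B subunit, fell from 64.4 ± 1.82 to 49.1 ± 2.27 CPM, and Gja1, the gap-junction protein connexin 43, from 224.2 to 180.8 CPM. The list as a group did not pass camera (adjusted p = 0.885). In contrast fry, which asks whether members move on balance one way, called it higher (adjusted p = 0.000809). The median log2 fold change of the list was -0.02, against 3.07 for Serpine2. Because fry was not run without Serpine2, its call cannot be told apart from the change in that gene. Inha was 13.7 ± 1.31 CPM in Con and 13.3 ± 1.30 in OP, and Foxl2 0.505 and 0.478 CPM, neither past the threshold. Of 16 luteinisation and steroidogenesis genes, 1 fell, the lipoprotein receptor gene Scarb1 with a log2 fold change of -0.14, and 0 rose (camera adjusted p = 0.564; 2 rose and 1 fell adjusted over the list alone). Of these, 5 rose and 1 fell without Con replicate 4. The call of Scarb1 was lost under 14 of 21 alternatives, among them leaving out any library but Con replicate 4 (adjusted p up to 0.101). Star was 0.916 and 0.788 CPM, not past the threshold. Amh (6 to 15 reads per library), Cyp19a1 (1 read, in OP replicate 1) and Hsd3b1 (1 read, in Con replicate 1) were too low to be tested. Fshr, Cyp11a1 and Lhcgr had no entry under these symbols in the deposited counts and were not analysed.

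Proteolysis and matrix genes also changed in both directions. Of 26 plasminogen and protease-inhibition genes, a list that includes Serpine2, 4 rose and 2 fell (4 and 4 adjusted over the list alone). The list did not pass camera (adjusted p = 0.917), and fry called it higher (adjusted p = 0.00254). Its median log2 fold change was -0.02, and fry was not run without Serpine2. Timp3, a metalloprotease inhibitor, rose from 84.1 ± 3.34 to 144.6 ± 4.09 CPM, and Adamts1, a protease of the ovulating follicle, fell from 98.9 ± 3.18 to 72.6 ± 3.57 CPM. Mmp9 rose with a log2 fold change of 1.22. Plat and Plau, encoding the plasminogen activators, had log2 fold changes of -0.19 and 0.16, neither past the threshold. Without Con replicate 4 both passed, at -0.26 and 0.28. Of 34 collagen and matrix genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.917), among them Lama4 at 1.23, Col18a1 at 0.69 and Col12a1 at 0.42, and Col4a1 at -0.28. Of 16 cumulus and ovulation genes, 3 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.917), including Ptx3, a matrix component of the expanded cumulus, at -0.32 and Runx1 at 0.39. Leaving out Con replicate 4 gave counts of risers and fallers of 10 and 9 for the plasminogen list, 10 and 16 for the matrix list and 7 and 5 for the cumulus list.

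The ERK feedback and immediate early list was higher in OP (camera adjusted p = 0.00829), with 9 of 28 members rising and 2 falling (10 and 2 adjusted over the list alone). With an estimated correlation its adjusted p = 0.526. Myc rose from 165.4 ± 2.05 to 292.5 ± 6.03 CPM, Egr1 from 53.2 ± 2.62 to 83.3 ± 6.72, and the feedback inhibitors Dusp4 and Spry4 had log2 fold changes of 1.15 and 0.72. Con replicate 4 itself differed from the other Con libraries by a median of 0.26 on this list, and without it 17 members rose and 3 fell. The ovarian surface epithelium list was also higher (camera adjusted p = 0.00991; adjusted p = 0.257 with an estimated correlation), where 2 of 5 members rose (3 adjusted over the list alone). Krt8, an epithelial keratin, rose from 11.2 ± 4.54 to 53.3 ± 2.49 CPM, and the gonadal transcription factor Lhx9 from 0.167 to 0.985 CPM. Con replicate 4 differed from the other Con libraries by a median of 0.52 on this list, and with no filter beyond 1 read its adjusted p was 0.182.

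Another 4 lists were lower in OP by camera, each by small amounts. Nuclear oxidative phosphorylation genes had a median log2 fold change of -0.09, with 5 of 49 falling, 0 rising (3 adjusted over the list alone; camera adjusted p = 0.00169; adjusted p = 0.983 with an estimated correlation). Ndufa4 and Cox4i1, respiratory-chain subunits, had log2 fold changes of -0.31 and -0.25, calls lost without OP replicate 2 or 4 and, for Cox4i1, 3 (adjusted p up to 0.0628 and 0.0631). Con replicate 4 lay 0.23 above the other Con libraries on this list. Without it 7 members rose and 11 fell, the median was -0.04 and the adjusted p was 0.197. G1/S and DNA replication genes had 3 of 34 falling and 1 rising, the same adjusted over the list alone (adjusted p = 0.0333; 0.983 as the adjusted p with an estimated correlation). Mcm2 had a log2 fold change of -0.22, a call lost without any library but Con replicates 1 and 4 (up to 0.108). Con replicate 4 lay 0.26 above the other Con libraries on it, and without it 8 rose and 9 fell and the adjusted p was 0.608. Among G2/M and mitosis genes 6 of 32 fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.0333; adjusted p = 0.257 with an estimated correlation and 0.0692 without Con replicate 1), including Cdk1 at -0.26, a call lost without Con replicate 2 or any OP library (up to 0.0991). With Con replicate 4 left out, 15 fell and 1 rose at an adjusted p of 0.0197, but 0.591 with an estimated correlation. The call was lost with library size only (0.0560) and on either FPKM scale (0.0548 and 0.0572). Mki67 was at 0.10, not past the threshold. Of 31 p53 targets and apoptosis genes, 7 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 0.0414; adjusted p = 0.429 with an estimated correlation). Without Con replicate 4 the counts were 16 and 3 and the adjusted p was 0.00203, but 0.666 with an estimated correlation. The call was also lost without Con replicate 1 (0.0692), 2 (0.0606) or 3 (0.127) and without OP replicate 1 (0.0550) or 4 (0.0967). Pmaip1 and Cdkn1a, a pro-apoptotic gene and a cell-cycle inhibitor, had log2 fold changes of -0.44 and -0.29 (the second lost without Con replicate 3 or any OP library, up to 0.0948), and the riser was the anti-apoptotic gene Bcl2 at 1.02. The cell-cycle lists and the p53 list also lost their calls with CPM of at least 1 in 4 libraries (0.0505, 0.0505 and 0.0551). With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05), and fry called 7.

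**Figure D3:**
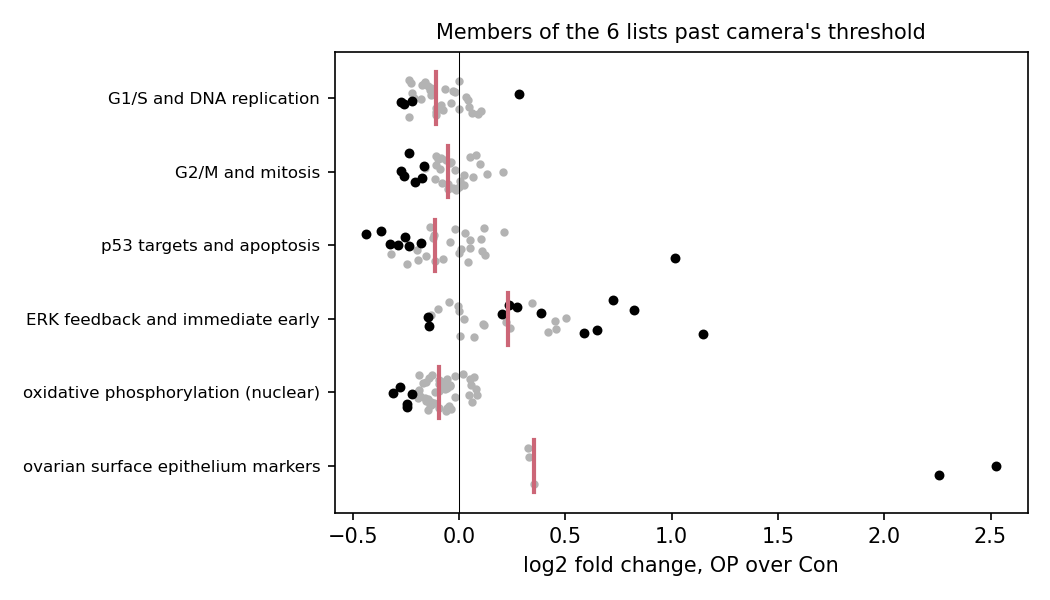
Log2 fold changes (OP over Con) of the members of the 6 lists past camera's threshold at the preset correlation; black points are genes past adjusted p 0.05, grey points are not, and coloured bars are list medians. Medians of the lower lists lie near 0, at -0.09 for oxidative phosphorylation, and that of the ERK list at 0.23.

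The remaining lists did not pass camera. Of 24 Hippo/YAP targets 3 rose and 4 fell, with the ectonucleotidase gene Nt5e at a log2 fold change of 2.40 (adjusted p = 0.564; 4 and 5 adjusted over the list alone). Of 17 Wnt targets 2 rose and 0 fell, with Nkd1 at 1.82 (adjusted p = 0.279; the same adjusted over the list alone), and fry called the list higher (adjusted p = 0.000416). Of 27 TGF-beta and activin targets 3 rose and 1 fell, with Tgfbi at 1.05 and Tgfb2 at -0.64 (adjusted p = 0.917; the same adjusted over the list alone). Of 37 interferon-response genes 4 rose and 0 fell, with Oas2 at 0.40 (lost without any library but Con replicates 3 and 4, up to 0.104) and Isg15 at -0.003 (adjusted p = 0.618; 0 adjusted over the list alone). Of 19 NF-kB and cytokine genes 1 rose and 2 fell (adjusted p = 0.778; 2 and 2 adjusted over the list alone). Cytosolic ribosomal proteins had 2 risers of 59 (0.349; the same adjusted over the list alone), cholesterol biosynthesis 1 faller of 24 (0.389; the same adjusted over the list alone) and unfolded protein response 1 riser of 34 (0.564; 0 adjusted over the list alone). Hypoxia and glycolysis had 3 risers and 2 fallers of 33 (0.960; the same adjusted over the list alone), and lysosome and autophagy 5 and 4 of 31 (0.693; 6 and 6 adjusted over the list alone).

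These counts moved when Con replicate 4 was left out. The interferon list, on which that library lay at a median of -0.25 relative to the other Con libraries, then had 10 risers and 9 fallers. Ribosomal proteins (0.27 in that library) then had 18 risers and 7 fallers, TGF-beta targets (0.33) 10 and 6, and the unfolded protein response (0.27) 7 and 5; camera's direction turned from down to up for these last lists, none past the threshold (adjusted p = 0.350, 0.401 and 0.736). Without Con replicate 1, by contrast, camera at the preset correlation called the ribosomal list lower (adjusted p = 0.0270). The estimated correlation of this list over all libraries was 0.883, where camera's adjusted p was 0.983. An estimated correlation was not used without Con replicate 1. Hypoxia and glycolysis (0.25) had 13 risers and 4 fallers, Hippo/YAP targets 6 and 11, Wnt targets 6 and 3, NF-kB and cytokine genes 5 and 4, cholesterol biosynthesis 3 and 2, and lysosome and autophagy 8 and 11.

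The theca, stromal fibroblast and smooth muscle lists did not pass camera, and fry called the last (adjusted p = 0.0280). Of 9 theca markers 1 rose and 1 fell (camera adjusted p = 0.917; the same adjusted over the list alone), namely Gli1 at 1.36 and Ptch1 at -0.21 (lost without any library but Con replicates 2 and 4, up to 0.0989). Of 9 stromal markers 1 rose (0.917; 0 adjusted over the list alone), and of 10 smooth muscle and pericyte markers 1 rose and 1 fell (0.917; the same adjusted over the list alone). Con replicate 4 lay at a median of -0.51 relative to the other Con libraries on theca markers and -0.38 on stromal markers. Without it 2 theca markers rose and 3 fell, 3 stromal markers rose and 5 fell, and 3 smooth muscle markers rose and 2 fell. Endothelial, macrophage and histone lists had only 4 tested members each, and among them 1 macrophage gene, Cd14, fell (lost without any library but Con replicates 1 and 4, up to 0.136); adjusted over the list alone, 1 endothelial gene also rose and 1 fell. Oocyte and mitochondrially encoded lists had 0.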

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

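The tests on Con replicate 4 in this part were chosen after its separation was seen. For each of 106 measures the 4 Con and the 4 OP values were checked, giving 212 sets that are not independent. In 22 sets a library's gap to the nearest other exceeded Dixon's critical value for 4 samples, where chance gives about 5 in 100 independent sets. Con replicate 4 was that library in 16 of these 22 sets. The other 6 were among the 106 OP sets, near the share that chance gives.

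Con replicate 4 lay below its group in TMM factor (0.947), in mean correlation with its group (0.985), on the second principal component (-33.0) and in log2 CPM of Disp2 (-2.58). It lay above its group in log2 CPM of Actg2 (5.42), Alpl (4.98), Bax (6.76), Dusp4 (3.93), Egln3 (6.48), Fen1 (6.69), Il6 (4.92), Mcm2 (8.48), Pfkl (9.40), Plau (5.92), Sprr1a (5.16) and Tnfrsf10b (6.15). Among the OP libraries, replicate 1 lay low in log2 CPM of Chst8 (2.96) and Kif20a (7.89) and high in Tgfb2 (4.99). OP replicate 2 lay high in Tgfbi (4.25) and in the median count of the tested genes (631), and OP replicate 3 lay high in Rsad2 (8.44).

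The tables argue against 3 explanations for Con replicate 4. An OP library under a Con label would carry OP levels of Serpine2, but its Serpine2 level of 142.0 CPM was 14.3% of the lowest OP library. Lower depth was not seen, since its total of 18096159 reads lay within the 17731048 to 19441504 of the other Con libraries. Gene length and GC content together went with 14.2% of the variance of its deviations over 9716 genes. Of 335 genes changed at least 2-fold between OP and Con replicates 1 to 3, 13.7% lay nearer OP in it, between the bounds set, so this test of an OP origin did not decide. A library from outside these groups under a Con label was not tested. Con replicate 4 had 33 Y-linked reads, against 28 to 42 in the other Con libraries and 185 to 258 in OP. On the first principal component it lay at -28.5, against -21.7 to -19.1 for the other Con libraries. The SD over chromosomes of the median log2 difference was at most 0.015 in splits within Con, against 0.071 between the groups. In Y-linked reads Con replicate 4 thus lay within the range of the other Con libraries. On the first component it lay on their side but beyond them. The splits within Con average it with another Con library, so they do not show its own chromosome shifts. These values do not settle the origin of Con replicate 4. No biological explanation was tested because the labels give none.

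Other splits of the libraries gave 0 called genes, but many gave as many list calls as the real grouping. Among the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave as many as 1621 called genes, 927 on the higher side or 694 on the lower, and the highest other split gave 0. For gene lists, 21 of the 35 splits gave at least the 6 calls of the real grouping, and the highest other splits gave 10. The list calls at the preset correlation were therefore no more numerous than in other splits. For the gene counts, 1 in 35 is the smallest share these splits can give. The other splits put Con and OP libraries together, which adds the group difference to the spread within each side. Their 0 gene calls therefore do not rule out chance, and they are no clean reference for the lists either.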

How the results depend on the processing

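Serpine2 stayed higher in OP under every alternative, at log2 fold changes of 3.02 to 3.15. All 89 named genes that were called kept their direction under the 21 alternatives that tested them (88 passed the stricter filter), and 25 of them kept their call under all. The count of genes higher in OP was 2275 with quality weights (which gave Con replicate 4 a weight of 0.0874), 233 against a fold of 1.5, 500 at an adjusted p of 0.01, and 618 to 2382 when each library was left out in turn. The count of genes lower in OP was 2113, 3, 215 and 321 to 2292 under the same settings. The highest of both ranges came without Con replicate 4. Same-numbered libraries did not deviate together (correlations of -0.05, 0.03, -0.01 and -0.05, none matching best with its own number), and the replicate block gave 644 genes higher and 310 lower.

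The number of gene lists higher in OP was 1 with no filter beyond 1 read, 1 with CPM of at least 1 in 4 libraries, 0 with an estimated correlation and 6 with fry; leaving out a library gave 2 throughout. The number of gene lists lower in OP was 1 with CPM of at least 1 in 4 libraries, 1 at an adjusted p of 0.01, 0 with an estimated correlation, 1 with fry and 2 to 4 without 1 library. The replicate block gave 2 higher and 3 lower, with p53 targets at an adjusted p of 0.0676. Causes were not tested.

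Some named genes that were not called changed sign near 0. The Foxl2 log2 fold change was 0.020 with limma-voom, 0.19 with quality weights and -0.33 to 0.14 when each library was left out in turn. The Isg15 log2 fold change was 0.022 with library size only, 0.0053 with upper quartile scaling, 0.017 with quality weights, 0.022 on either FPKM scale and -0.021 to 0.016 with a library left out. The Mki67 log2 fold change was -0.00597 with quality weights and -0.023 to 0.16 with a library left out. With a library left out, the Inha log2 fold change ranged from -0.11 to 0.0023. In simulation, 1.5-fold changes were recovered for 82.1% of genes, so changes smaller than that can be missed. No simulated library was set apart as Con replicate 4 was, so this rate may not carry over to these data.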

Other observations

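The tests in this part were chosen after the values were seen, except the comparison of chromosome shifts with differences inside a group. Among genes at least 2-fold higher in OP, the deposited GO annotation was enriched for axon guidance, with 13 of 126 tested members against 2.92 expected (one-sided hypergeometric test, adjusted p = 0.0142). The members included the netrin gene Ntn1 and its receptor gene Unc5a, Reln and Sema3e. Potassium ion transmembrane transport had 6 of 32 members, with channel genes such as Kcnh2 (adjusted p = 0.0410). B cell receptor signaling had 5 of 20 (adjusted p = 0.0410), and synaptonemal complex 5 of 19 (adjusted p = 0.0410), of which Xlr and Xlr3c belong to a family of similar copies and are uncertain. No KEGG pathway was enriched by this test. Of the 292 rises of at least 2-fold, 170 were of genes with a Con mean below 1 CPM. The background, all tested genes with an annotation, was not matched for expression level. These terms therefore cannot be told apart from a property of low-expressed genes. With camera, 4 of 297 KEGG pathways were lower, led by oxidative phosphorylation (adjusted p = 0.00628). None of the 4 held without Con replicate 4 or with an estimated correlation, and 0 of 2058 GO terms passed (122 at an unadjusted p under 0.05).

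Y-linked transcripts and near-silent genes were higher in OP, and median fold changes differed between chromosomes, assigned with GRCm38. At the extremes, the median log2 fold change was 0.16 on chromosome 12, where 88.3% of 332 genes lay above 0, and -0.12 on chromosome 14, where 13.8% of 318 did. Several other chromosomes also shifted, among them 19 at -0.114 (16.9% above 0), 6 at -0.111 (23.0%), 8 at -0.108 (21.7%) and 1 at 0.070 (72.8%). Little shift was seen on chromosomes 15, 16 and X, with 46.3%, 46.4% and 47.9% above 0. Liver RNA as the source of the Y-linked reads is argued against, since Alb reads were at most 1.995 times the Y-linked reads in an OP library. A fixed share of X-linked homolog reads assigned to the Y-linked genes is argued against too, since each of the 4 Y-linked genes exceeded its homolog by a log2 fold change of at least 1.84 (standard error 0.27). A share that was higher in OP stays open, because the homologs had a median log2 fold change of -0.070 and a gain of 1.09% of their level is too little to show in it. The SD of the chromosome medians, 0.071 over 9852 genes, exceeded all 10000 permuted assignments (permutation p = 0.0001, the smallest they can give), and the spread between groups was 4.77 times the largest of the 2-against-2 splits within a group. For the chromosome shifts, a candidate explanation is that the OP and Con cells differed in chromosome copy number, as separately derived cell populations might. An effect of the treatment itself cannot be separated from this, because the groups coincide with it. Neither was tested for the Y-linked transcripts or the near-silent genes. The labels name ovaries as the origin of the cells and give no source for Y-linked reads in either group.

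Liver transcripts were found in all 8 libraries, with Alb at 434 to 911 reads in Con and 315 to 419 in OP. Major urinary protein transcripts, which are near-identical copies most abundant in male liver, had 27 to 54 reads in Con and 183 to 264 in OP. Major urinary protein reads per Alb read were 9.94 times higher in OP, which argues against a shared liver source for both kinds of transcript. A shared source of Alb alone stays open, because the OP cells may have made the major urinary protein transcripts. The ratio also varied within Con, with 35 major urinary protein and 911 Alb reads in replicate 1 and 54 and 434 in replicate 3. All 20 liver genes were higher in Con replicate 1 than in each other Con library, that is 100% in 1 direction. Of 10000 random lists of like level, each given the pair of Con libraries where its own share was highest, 4 reached this (permutation p = 0.0005). RNA or reads from outside the cultures, in amounts that differ between libraries, may account for these transcripts. Between OP and Con, however, the 20 genes did not move together: 6 fell and 0 rose. Fgb was at -1.54 and Apob at -1.07, while Apoa1 was at 0.05, Hp at 0.07 and Cyp2e1 at 0.39, these last not past the threshold. A lower amount alone would move them alike, so whether it accounts for the falls of Fgb, Apob and Gc is left open. Expression by the cells themselves was not tested.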
